A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

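The data were RNA sequencing libraries of mammary carcinoma cell lines kept for 48 hours in medium of pH 6.4 or pH 7.4. MDA-MB-231 is a human breast cancer line and 4T1 is a mouse mammary tumour line. The low pH was set through the bicarbonate of the medium, per the labels. Cells at passage 4 and 70% confluency were used, total RNA was extracted and libraries were made with the KAPA Hyper Prep kit and read as 75 bp pairs on a NextSeq500, per the labels' protocols. There were 2 MDA-MB-231 libraries at each pH, 2 4T1 libraries at pH 7.4 and 1 4T1 library at pH 6.4. Each library was placed in its group by its title, and no label says that the libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

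For each line the authors deposited a table of reads per gene and a table of reads per exon part. The deposited gene values are whole numbers, taken here to be expected counts: per the submitters' processing notes, the reads were handled with FastQC, STAR 2.5.3 and RSEM 1.3.0 on the builds GRCh38 and GRCm38, and RSEM estimates a count per gene. How the values came to be whole numbers is not given in the sources used here. The exon values are deposited counts of reads per numbered part of a gene. The role of each tool, the annotation release, the filters and the strand setting are not given in the sources used here. Reads of a gene and of an antisense or overlapping gene can therefore not be told apart, and reads of near-identical copies such as ribosomal protein genes and their pseudogenes, HLA genes and histone genes may have been divided between them by the estimate, so their values are uncertain. A read that spans several exon parts is counted in each of them, so the p-values of the exon test are too small.

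Gene counts totalled 19712889 to 43075290 per MDA-MB-231 library and 23301193 to 33239196 per 4T1 library. In each line 1 entry among the gene counts and 5 among the exon counts name no gene, and these were left out of totals and tests. Reads counted outside annotated exons were 5.61 to 10.99% of the exon-level counts of a library. Reads that fitted more than 1 gene were 0.028 to 0.14%. Exon-level counts are these reads plus all exon part counts. A read can add to several parts, so the shares of reads may be higher. Floors and intervals from counts cover counting error only.

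Each line was fitted alone with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and the pH effect was tested with edgeR's quasi-likelihood F test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. In MDA-MB-231 this left 2 residual degrees of freedom. In 4T1 it left 1, from the pH 7.4 libraries, and the lone pH 6.4 library was assumed to vary like them. The prior degrees of freedom were 4.78 for MDA-MB-231 genes and infinite for 4T1 genes and exon parts. A 4T1 p-value therefore rests on the spread fitted over all genes or parts, not on that of its own gene. The difference of the pH effects was tested as an interaction in 1 fit of all 7 libraries over the 16521 symbols found once in both gene tables when written in capitals. Exon usage was tested with diffSpliceDGE, which asks whether an exon part changed relative to the rest of its gene, with the Simes p per gene. Its coefficients were converted from natural logarithms to log2. Levels are in CPM, the counts scaled to a common library size with the TMM factors applied (cpm in edgeR). A gene whose libraries of a group were all at 0 was set against a floor of 3 counts per library.

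Before the data were examined, 41 gene lists were fixed: acid transport and sensing, lysosome and V-ATPase, autophagy, cholesterol synthesis and uptake, cholesterol efflux, fatty acid synthesis, fatty acid oxidation and lipid storage, glycolysis and lactate, hypoxia response outside glycolysis, oxidative phosphorylation, citric acid cycle, DNA replication, mitosis, replication-dependent histones, the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock, oxidative stress, MondoA targets, p53 targets, matrix proteolysis, collagens and matrix proteins, integrins and focal adhesion, actin motility, mesenchymal markers, epithelial markers, TGF-beta targets, YAP targets, interferon-stimulated genes, antigen presentation, inflammatory cytokines, splicing regulators, ribosomal proteins, ribosome biogenesis, immediate early genes, apoptosis regulators, S100 proteins, mitochondrially encoded transcripts, and markers of leukocytes, of fibroblasts and of endothelium and erythrocytes. Lists with at least 3 tested genes entered limma 3.58.1 camera with a preset correlation of 0.01. The list of endothelium and erythrocyte markers had too few tested genes in either line and was not tested, which left 40 lists.

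The genes named were chosen by a rule fixed at the same time. For each line it took, among genes with a symbol, a mean of at least 10 CPM, an adjusted p of at most 0.05 and no overlap between the pH groups, the 8 largest rises and the 8 largest falls, then the 3 rises and 3 falls of smallest p beyond these. It added the 2 members of smallest p in each list past its threshold and in the lists of acid transport, matrix proteolysis, splicing regulators and lysosome, 16 genes whatever their values (among them LAMP2, MMP14, CD44, ENAH, CA9, CA12, SLC16A3, GPR65, TXNIP, VEGFA, MKI67, LDHA, HMGCS1 and ESRP1), and the 5 genes of smallest p in each direction for the difference between lines with at least 10 CPM in each. For exon usage it took the 6 genes per line of smallest p whose most changed part moved by at least 1 on the log2 scale with a mean of at least 20 counts, and CD44 and ENAH. Not every gene that the rule takes is reported here.

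Human exon parts were placed in GENCODE release 29 on GRCh38, where 94.7% of the genes of the exon table had the same number of parts. Parts of the other genes were given no position. With the parts numbered along the genome, the median rank correlation of a part's count with its length was 0.325 on the + strand and 0.314 on the - strand, against -0.1 with the numbering reversed. No mouse annotation was used here, so mouse parts carry numbers only. The transcript length of the longest annotated transcript was known for 99.7% of the tested MDA-MB-231 genes. Only 75.4% of the tested 4T1 genes had a human gene of the same symbol with a length, under the 80% set as the minimum, so the length check was void in 4T1.

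The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a fold threshold of 1.5 (glmTreat), a joint fit, a replicate block, leaving out each library and, for lists, an estimated correlation and fry. Scaling by library totals and removal of the length trend (loess, span 0.5) were added after the data had been seen. The tests were checked on simulated counts with changes of known size, drawn from the means and spread of these libraries. For MDA-MB-231, edgeR found 56% of 2-fold and 75.2% of 4-fold changes among 14509 simulated genes, and 13.9% of its calls were false. For 4T1 it found 69.8% and 90.1% among 14123, with 7.6% false. Both false shares lie above the nominal 5%. The difference between lines found 49.6% and 92.4% among 9874, with 3.1% false. The exon test found 42.9% of the genes with a 4-fold changed part in MDA-MB-231, with 20.4% of calls false among 11322 genes, and 57.1% in 4T1, with 2.6% false among 11291. Camera called 0 lists in simulations with no changed list. Simulated genes were drawn independently of one another, so this cannot test whether the preset correlation is adequate. Few genes were changed in the simulations, such as 91 by 2-fold and 105 by 4-fold for MDA-MB-231. Far more were called in the real libraries, so the false shares need not carry over to those calls. Figures were drawn with matplotlib.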

Results

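Gene expression was measured in 7 RNA sequencing libraries from a human breast cancer line, MDA-MB-231, and a mouse mammary tumour line, 4T1, after 48 hours in medium of pH 6.4 or pH 7.4. The pH 7.4 libraries served as the controls. MDA-MB-231 had 2 libraries at pH 6.4, with gene counts totalling 28038377 and 19712889, and 2 at pH 7.4, with 34575235 and 43075290. 4T1 had 1 library at pH 6.4, with 23301193, and 2 at pH 7.4, with 30162122 and 33239196. The log2 CPM of the pH 6.4 replicates of MDA-MB-231 correlated across genes with r = 0.971, the pH 7.4 replicates with r = 0.994 and the pH 7.4 replicates of 4T1 with r = 0.989. Genes are not independent replicates. Each library was counted as 1 sample.

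The first comparison asked which genes responded to acidic medium in MDA-MB-231. Cytokine and stress response genes were among the largest rises, and genes of DNA replication fell. CSF2, which encodes the cytokine GM-CSF, rose from 0.332 ± 0.21 to 76.1 ± 11.5 CPM (SD, n = 2), a log2 fold change of 7.89 with a standard error (SE) of 0.292. Its value was 8.64 without pH 7.4 replicate 1 and 7.26 without pH 7.4 replicate 2, as both controls lay near 0. The chemokine genes CXCL2, CXCL3 and CXCL8 rose by 7.13, 6.92 and 5.96 on the log2 scale, and the phosphatase gene DUSP1 by 6.99. The circadian repressor gene CIART (6.04), the pyruvate dehydrogenase kinase gene PDK4 (5.78) and SAT1, an enzyme of polyamine breakdown (5.78), completed the 8 largest rises. The largest fall was that of the phosphodiesterase gene PDE7B, from 25.1 ± 2.78 to 0.342 ± 0.0359 CPM (SD, n = 2), with a log2 fold change of -6.17 and an SE of 0.252. FAM111B (-6.07), SAMD9 (-5.54), KLHL4 (-5.34), TICAM2 (-5.24), FLRT2 (-5.12), EVI2B (-5.10) and TRERF1 (-5.08) followed. The values and the order of some of these depend on 1 library: without pH 6.4 replicate 1 SAMD9 was at -7.12, FLRT2 at -6.32 and EVI2B at -6.46, and without pH 6.4 replicate 2 SAMD9 was at -4.94 and TICAM2, which had 0 CPM in that library, at -4.42. Without pH 6.4 replicate 1, TICAM2 has only that library at 0 and no finite fold. Among the genes of smallest p beyond these, the stress genes PPP1R15A (5.75) and GADD45A (5.33) and the transcription factor gene MAFF (4.47) rose, and the replication genes CDC6 (-3.53) and MCM3 (-4.08) and the growth factor gene BMP4 (-4.02) fell. Adjusted p-values of these 22 genes lay between 7.14e-07 and 0.000242 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

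In all, 10170 of 14969 tested MDA-MB-231 genes changed, of which 4771 rose and 5399 fell. At least 2-fold changes were seen in 2935 risen and 3905 fallen genes. The pH 6.4 libraries differed from the controls in makeup: their 10 most abundant genes held 13.33 and 11.89% of the counts, against 4.98 and 5.38%. Their reads outside annotated exons were 8.9 and 10.99% of the exon-level counts, against 5.74 and 5.81%. Scaling by library totals instead of TMM moved the median log2 fold change by -0.68 and gave 2601 risen and 8216 fallen genes. The fold change also fell with transcript length, from a median of 0.715 (log2) in the 10% of genes with the shortest transcripts to -0.722 in the 10% with the longest, and removing this trend gave 5698 risen and 4225 fallen genes.

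Inflammatory, stress and protein-folding genes rose as groups in MDA-MB-231. Of 28 tested inflammatory cytokine genes, 22 rose and 1 fell, with a median log2 fold change of 3.10, and LIF rose by 3.13 (camera adjusted p = 9.02e-14, adjusted p = 0.28 with an estimated correlation). Of 19 immediate early genes, which answer within minutes to signals in many cells, 16 rose and 1 fell, with a median of 2.39. MYC rose from 50.5 to 1343 CPM, a log2 fold change of 4.73 (camera adjusted p = 3.1e-12, adjusted p = 0.28 with an estimated correlation). Of 21 ER chaperone and unfolded protein response genes, 20 rose, with a median of 1.48. HSPA5, the ER chaperone BiP, rose from 939 ± 4.64 to 13643 ± 30.4 CPM (SD, n = 2), and DNAJB9 rose by 3.92 on the log2 scale (camera adjusted p = 1.62e-12, adjusted p = 0.28 with an estimated correlation). Of 29 targets of ATF4, the transcription factor of the integrated stress response, 18 rose and 2 fell, with ATF3 at 5.59 (camera adjusted p = 2.09e-08, adjusted p = 0.28 with an estimated correlation). All 5 targets of MondoA, a glucose-sensing transcription factor, rose: TXNIP by 3.82, ARRDC3 by 4.10 and ARRDC4 by 3.66 among them (camera adjusted p = 3.39e-08, adjusted p = 0.28 with an estimated correlation).

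Genes of the cell cycle fell in MDA-MB-231. Of 34 DNA replication genes, 32 fell and 1 rose, with a median log2 fold change of -2.06 (camera adjusted p = 5.1e-18, adjusted p = 0.304 with an estimated correlation). Of 32 mitosis genes, 25 fell and 4 rose, with a median of -0.95 (camera adjusted p = 1.44e-07, adjusted p = 0.28 with an estimated correlation). MKI67, the proliferation marker Ki-67, fell by 3.89 on the log2 scale and the kinesin gene KIF11 by 2.75.

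Lysosomal, autophagy and cholesterol genes rose. Of 45 lysosome and V-ATPase genes, 34 rose and 2 fell, with a median of 1.03, and the proton pump subunits ATP6V1B2 and ATP6V1G1 rose by 1.78 and 2.31 (camera adjusted p = 7.84e-08, adjusted p = 0.28 with an estimated correlation). Autophagy genes rose in 14 of 21 cases and fell in 4, among the risen GABARAPL1 (3.30) and MAP1LC3B (2.54), but their median of 0.49 turned to -0.19 with library totals (camera adjusted p = 0.000597, adjusted p = 0.45 with an estimated correlation). Of 24 cholesterol synthesis genes, 18 rose and 4 fell, with a median of 1.25, and HMGCS1 at 3.31 (camera adjusted p = 4.63e-06, adjusted p = 0.469 with an estimated correlation). All 34 ribosomal protein genes rose, with a median of 1.44, RPLP1 at 2.48 and RPL5 at 1.70 (camera adjusted p = 2.17e-10, adjusted p = 0.557 with an estimated correlation). Ribosome biogenesis genes rose in 22 of 32 cases and fell in 5, with the polymerase subunit gene POLR1C at 3.08 (camera adjusted p = 2.41e-06, adjusted p = 0.469 with an estimated correlation). Splicing regulators rose in 39 of 61 cases and fell in 10, with the kinase gene CLK1 at 3.64 and HNRNPH3 at 2.44, and their median of 0.71 became 0.03 with library totals (camera adjusted p = 4.85e-06, adjusted p = 0.469 with an estimated correlation).

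The other lists past the threshold were antigen presentation, the hypoxia response outside glycolysis and oxidative stress. Of 15 antigen presentation genes 11 rose and 1 fell, with HLA-E at 3.08 and HLA-B at 2.89 (camera adjusted p = 2.35e-06, adjusted p = 0.304 with an estimated correlation). Of 22 hypoxia genes 14 rose and 5 fell, with BHLHE40 at 4.71 and MXI1 at 3.15 (camera adjusted p = 0.000305, adjusted p = 0.487 with an estimated correlation). Of 19 targets of NRF2, the regulator of the oxidative stress response, 11 rose and 4 fell, with MGST1 at 2.19 and the ferritin gene FTH1 at 2.44 (camera adjusted p = 0.00424, adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, the counts of all 16 lists were the same, except for 19 risen ATF4 targets, 12 risen NRF2 targets, 3 fallen lysosome genes and 11 fallen splicing regulators. No list kept its call with an estimated correlation. Lysosome genes had an estimate of 0.001, below the preset value, yet an unadjusted camera p of 0.0217 against 1.57e-08. Mitosis genes, with an estimate of -0.029, had 0.0241 against 3.24e-08. The other lists had estimates above the preset value, up to 0.938 for ribosomal proteins. For lysosome and mitosis genes the loss does not come from a higher correlation. For the other lists a higher correlation may have added to the loss, but its part cannot be told from that of the setting itself. Ribosomal proteins went from an unadjusted camera p of 2.71e-11 to 0.307, a larger p than that of lysosome genes.

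**Figure D1:**
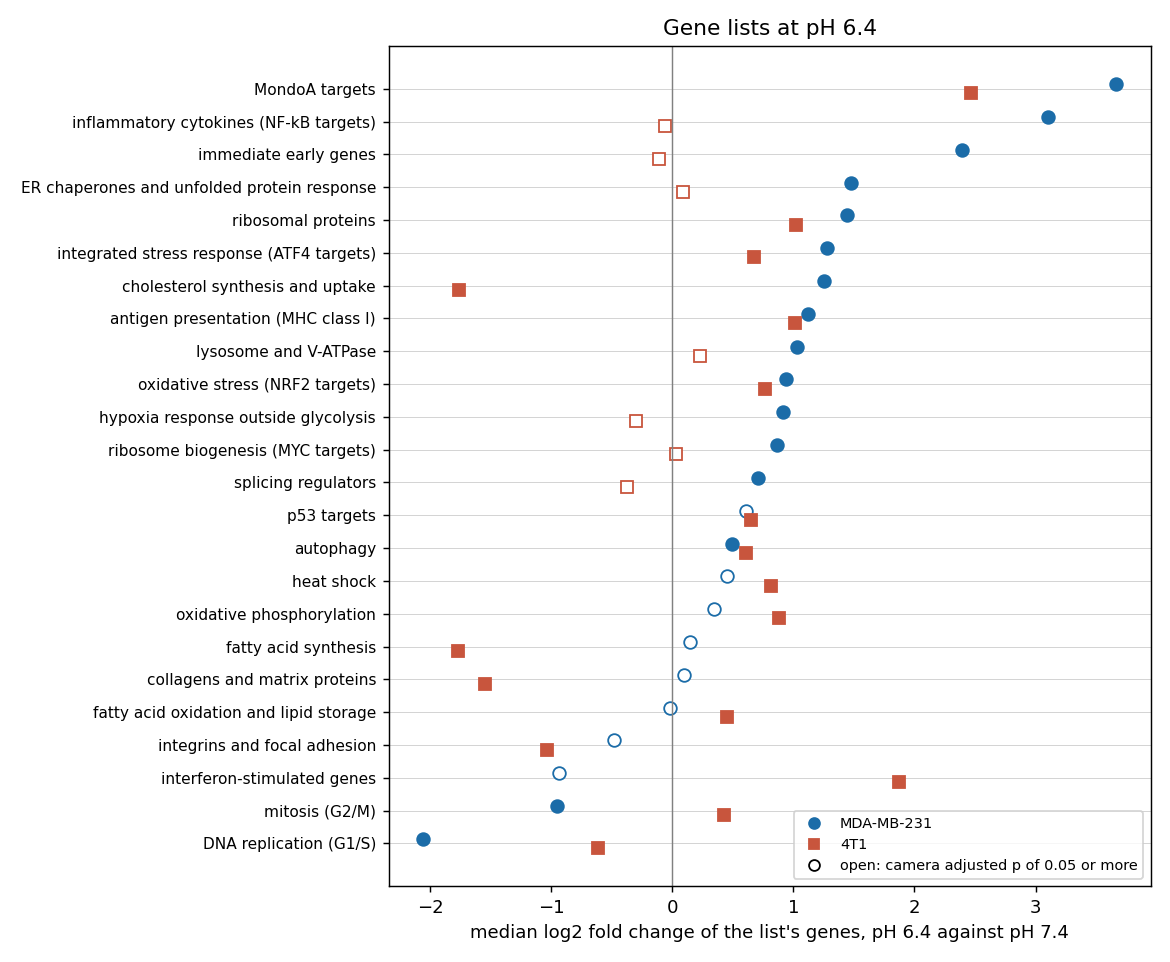
Median log2 fold change of each gene list at pH 6.4 against pH 7.4 (x axis) for the lists past the camera threshold in either line (y axis), with circles for MDA-MB-231 and squares for 4T1, filled where the line's own test passed. Cholesterol synthesis lies at 1.25 in MDA-MB-231 and -1.765 in 4T1, but with library totals the MDA-MB-231 medians of autophagy (-0.188), oxidative phosphorylation (-0.343), heat shock (-0.229), p53 targets (-0.074), collagens (-0.586) and fatty acid synthesis (-0.539) turn negative and so does ribosome biogenesis in 4T1 (-0.014), while fatty acid oxidation in MDA-MB-231 turns to 0.014 with DESeq2 size factors and the inflammatory cytokines in 4T1 to 0.004 with upper quartile factors.

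Genes of acid handling and invasion were examined one by one. LAMP2, a lysosomal membrane protein gene on chromosome X (120427827 to 120469365, GRCh38, ENSG00000005893), rose from 269 ± 2.12 to 604 ± 42.1 CPM (SD, n = 2), with a log2 fold change of 1.17 and an SE of 0.0772. The matrix metalloprotease gene MMP14 (chromosome 14, 22836557 to 22849027, ENSG00000157227) rose by 0.73 with an SE of 0.0836, but its value fell to 0.05 and out of significance with library totals. ENAH, an actin regulator gene (chromosome 1, 225486835 to 225653142, ENSG00000154380), rose by 1.37. The adhesion receptor gene CD44 (chromosome 11, 35138870 to 35232402, ENSG00000026508) stood at 952 ± 13.7 CPM at pH 7.4 and 1068 ± 54.8 CPM at pH 6.4 (SD, n = 2), a log2 difference of 0.16 that did not pass (adjusted p = 0.0805 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call for CD44 in MDA-MB-231 depended on the setting: it passed as a rise in limma-voom (0.16), with the length trend removed (0.71) and without pH 6.4 replicate 1 (0.19), and as a fall with library totals (-0.51). Of 19 acid transport and sensing genes, 2 rose and 9 fell, or 2 and 8 adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.471). The bicarbonate transporter gene SLC4A7 rose by 1.78, while SLC4A2 (-1.91), the lactate transporter gene SLC16A3 (-1.27) and the carbonic anhydrase gene CA12 (-0.65) fell. The CA12 call was lost with the length trend removed (-0.05), with a fold threshold, and without pH 7.4 replicate 1 (-0.50). CA9 was at 1.85 CPM against 1.03 (log2 0.85, SE 0.424) and did not pass, except without pH 6.4 replicate 2 (1.05). GPR65 and ESRP1, with 1 and 12 counts over the 4 libraries, were not tested. Of 27 matrix proteolysis genes 13 rose and 8 fell, also adjusted over the list alone, with MMP1 at 2.67 and PLAUR at 2.16, and the list did not pass (camera adjusted p = 0.57). VEGFA rose by 0.98, and LDHA, the lactate dehydrogenase A gene, fell by 1.58 on the log2 scale. The genes called changed here had adjusted p-values of 3.74e-06 (LDHA) to 0.016 (CA12) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

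The same comparison in 4T1 rests on 1 library at pH 6.4. Stress and interferon genes were among the largest rises. Cx3cr1, a chemokine receptor gene, rose from 0.231 ± 0.0931 CPM (SD, n = 2) to 31.5 CPM, a log2 fold change of 7.05 with an SE of 0.287. The stress genes Gadd45b (5.70), Ddit3 (4.96) and Atf3 (3.84), the interferon-induced genes Gbp2b (4.20), Oas3 (4.04) and Xaf1 (3.82) and the quinone reductase gene Nqo1 (4.11) followed. Cyp24a1, the enzyme of vitamin D breakdown, had 0 counts at pH 6.4 against 25.7 ± 0.763 CPM at pH 7.4 (SD, n = 2), and was at least 196-fold lower against a floor of 3 counts in the pH 6.4 library. The mitochondrial gene mt-Co3 had 2 counts at pH 6.4 against 3194 and 9206, a 2162-fold lower level with a 95% counting interval of 598 to 17852 (Poisson) that leaves out the spread of the controls (fitted log2 value -11.01, and -10.12 in the joint fit without pH 7.4 replicate 2), while the gene model Gm29216, chosen after its values were seen, went from 1058 and 874 counts to 26732. Dio2, a thyroid hormone deiodinase gene, fell by 6.98 on the log2 scale, and Lilr4b (-6.90), Trib2 (-6.63), Itga8 (-6.50), Hhip (-6.46) and F5 (-6.25) fell as well. Among the genes of smallest p beyond these, Brd2 (3.27), Gbp2 (3.49) and Snrnp48 (3.05) rose, and Etv1 (-4.74), Itga1 (-4.85) and Arhgap18 (-4.12) fell.

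In 4T1, 9195 of 14538 tested genes changed, of which 4385 rose and 4810 fell, and 2306 rose and 2805 fell at least 2-fold. Against a fold of 1.5, 5649 genes passed. In the joint fit without 1 pH 7.4 library, 5733 (without replicate 1) or 5615 (without replicate 2) passed. In the pH 6.4 library, reads outside annotated exons were 9.52% of the exon-level counts, against 5.61 and 6.61%. Its 10 most abundant genes held 7.5% of its gene counts, against 4.99 and 6.08%.

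Interferon, ribosomal and respiratory chain genes rose in 4T1. Of 31 interferon-stimulated genes, 27 rose and none fell, or 27 and 1 adjusted over the list alone, with a median log2 fold change of 1.87 (camera adjusted p = 1.49e-16, adjusted p = 0.619 with an estimated correlation). All 34 ribosomal protein genes rose, with a median of 1.02, Rps23 at 1.44 and Rpl22 at 1.33 (camera adjusted p = 1.47e-13, adjusted p = 0.619 with an estimated correlation). Of 34 oxidative phosphorylation genes 33 rose, with Sdhd at 1.86 and Ndufs3 at 1.51 (camera adjusted p = 8.32e-10, adjusted p = 0.619 with an estimated correlation). Antigen presentation genes rose in 11 of 14 cases and fell in 2, with H2-K1 at 389 CPM against 138 and the proteasome activator gene Psme2 at 1.38 (log2) (camera adjusted p = 0.000497, adjusted p = 0.619 with an estimated correlation). Of 5 MondoA targets 4 rose and 1 fell, with Txnip at 2.99 and Pfkfb3 at 2.55 (camera adjusted p = 5.94e-06, adjusted p = 0.619 with an estimated correlation).

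Lipid synthesis and matrix genes fell in 4T1. Of 23 cholesterol synthesis genes, 22 fell and none rose, with a median of -1.76, Idi1 at -2.62 and Hmgcs1 at -1.34 (camera adjusted p = 7e-13, adjusted p = 0.619 with an estimated correlation). Of 15 fatty acid synthesis genes 12 fell and 2 rose, with the elongase gene Elovl6 at -3.77 and the desaturase gene Fads2 at -3.37 (camera adjusted p = 3.2e-08, adjusted p = 0.619 with an estimated correlation). Of 30 collagen and matrix protein genes 19 fell and 3 rose, with osteopontin (Spp1) at -3.26 and the laminin gene Lama5 at -2.56 (camera adjusted p = 3.34e-07, adjusted p = 0.619 with an estimated correlation). Of 24 integrin and focal adhesion genes 16 fell and 2 rose, with Itga3 at -2.82 (camera adjusted p = 5.6e-07, adjusted p = 0.619 with an estimated correlation).

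Stress lists moved up with mixed members. Of 17 NRF2 targets 13 rose, among them Nqo1, and 2 fell, among them the cystine transporter gene Slc7a11 (-3.40) (camera adjusted p = 8.16e-05, adjusted p = 0.619 with an estimated correlation). Of 28 ATF4 targets 17 rose and 6 fell (camera adjusted p = 0.0003, adjusted p = 0.683 with an estimated correlation). Heat shock genes rose in 10 of 12 cases and fell in 1, with Hspb1 at 3.36 and Hspe1 at 1.34 (camera adjusted p = 0.00211, adjusted p = 0.619 with an estimated correlation). Autophagy genes rose in 16 of 21 cases and fell in 2, with Atg14 at 2.33 and Sqstm1 at 1.11 (camera adjusted p = 0.00281, adjusted p = 0.633 with an estimated correlation). Of 18 p53 targets 9 rose and none fell, with the death receptor gene Fas at 2.39 and Trp53inp1 at 1.43 (camera adjusted p = 0.00706, adjusted p = 0.619 with an estimated correlation). Fatty acid oxidation genes rose in 12 of 23 cases, or in 11 adjusted over the list alone, and fell in 1, with Cpt2 at 1.51 and Acot2 at 2.07 (camera adjusted p = 0.026, adjusted p = 0.818 with an estimated correlation).

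The cell cycle lists of 4T1 moved apart. Of 34 DNA replication genes 21 fell and 6 rose, or 21 and 7 adjusted over the list alone, with Rrm2 at -1.87 and Tyms at -1.98 (camera adjusted p = 0.00706, adjusted p = 0.619 with an estimated correlation). Of 32 mitosis genes 20 rose and 6 fell, with a median of 0.43 (camera adjusted p = 0.0336, adjusted p = 0.619 with an estimated correlation). Pttg1 (2.17) and the kinase gene Aurka (2.04) rose, while Mki67 fell by 2.25 on the log2 scale. Adjusted over the list alone, the counts of the 17 lists past the threshold differed only as given above. Of lists that did not pass, 12 splicing regulators rose and 33 fell of 61, or 12 and 35 adjusted over the list alone (camera adjusted p = 0.0626), with Hnrnpa0 at -2.35 and Mbnl3 at -2.28. Of 43 lysosome genes 19 rose and 13 fell, also adjusted over the list alone (camera adjusted p = 0.368), and Gpnmb (-1.85) and Asah1 (-1.51) fell.

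Most of the acid handling and invasion genes named for 4T1 fell or did not pass, but Adamts1 and Vegfa rose. Lamp2 stood at 516 CPM at pH 6.4 and 469 ± 53.4 CPM at pH 7.4 (SD, n = 2) and did not pass. Mmp14 (-0.92), Cd44 (-1.77), Enah (-1.58) and Car9 (-1.17), the mouse CA9, fell, the last not in DESeq2, whose test it missed with a log2 value of -1.14. Car9 was at 3.68 CPM at pH 6.4 against 4.49 and 11.99 CPM at pH 7.4, so the size of its fall rests on pH 7.4 replicate 2. Of 13 acid transport genes 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.175), with Slc4a4 at -1.96 and Slc4a8 at -3.28. The log2 values of Car12 (-0.23, SE 0.14) and Ldha (-0.13, SE 0.13) did not pass, except that of Ldha in the joint fit without pH 7.4 replicate 1 (-0.31). Slc16a3 and Gpr65, with 0 and 16 counts over the 3 libraries, were not tested. Of 30 matrix proteolysis genes 6 rose and 17 fell, or 6 and 18 adjusted over the list alone (camera adjusted p = 0.155), with the metalloprotease gene Adamts1 at 2.28. Vegfa rose by 1.72. Esrp1, an epithelial splicing regulator gene, fell by 0.52 on the log2 scale, a call lost in DESeq2 (-0.50), in the joint fit (-0.47), against a fold of 1.5 and without either pH 7.4 library (-0.65 and -0.27). Named 4T1 genes called changed had adjusted p-values of 3.29e-247 to 0.0125 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These rest on 1 library at pH 6.4 and on a spread fitted over all genes. The smallest was that of mt-Co3, whose pH 7.4 libraries stood at 105 and 273 CPM.

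**Figure D2:**
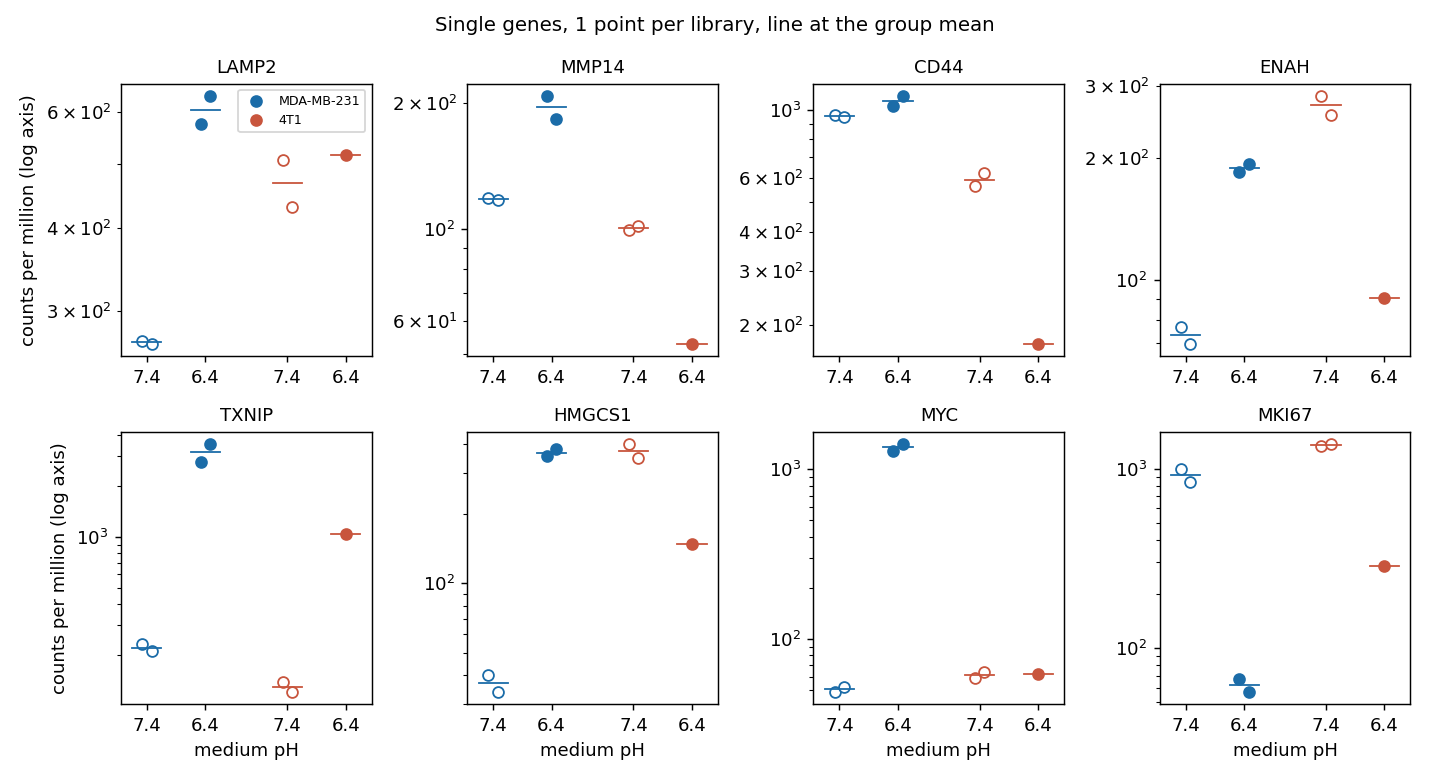
CPM on log axes (y) of 8 genes by medium pH (x), with 1 point per library, filled at pH 6.4 and open at pH 7.4, and a line at each group mean (n = 2, or 1 for 4T1 at pH 6.4). HMGCS1 is higher at pH 6.4 in MDA-MB-231 (368 against 37.0 CPM) and lower in 4T1 (148 against 374 CPM), while CD44 in MDA-MB-231 turns from 0.16 to -0.51 on the log2 scale with library totals.

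The third comparison asked whether the lines differed in their response. In a single fit of all 7 libraries, the pH effect differed for 6312 of 12186 genes, being higher in MDA-MB-231 for 2761 and lower for 3551 (3198 and 3076 with TMM factors computed within each line), and 1431 of them passed in opposite directions. In the separate fits the polyamine gene SAT1 rose in both lines, by 5.78 in MDA-MB-231 and 1.31 in 4T1. TM4SF1 (2.60 and -1.94), the isoprenoid enzyme gene IDI1 (2.88 and -2.62) and the phosphatase gene DUSP6 (0.79 and -3.79) rose in MDA-MB-231 and fell in 4T1, and MYC rose in MDA-MB-231 with a 4T1 value of 0.02 that did not pass. The rise of DUSP6 in MDA-MB-231 was lost with library totals (0.11). NQO1 (-0.80 and 4.11), AURKA (-1.75 and 2.04), HYLS1 (-3.28 and 1.13) and MCM4 (-2.65 and 0.56) fell in MDA-MB-231 and rose in 4T1, the last not against a fold of 1.5, and MCM3 fell in MDA-MB-231 with a 4T1 value of -0.16 that did not pass. Adjusted p-values of these 10 differences were 4.54e-09 to 2.21e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

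The changes of the lines overlapped. Of 9865 genes tested in both, 1722 rose in both, against 1127.1 expected of independent lists (odds ratio 3.27, 95% interval 2.99 to 3.58, Fisher's exact test p = 3.05e-155), and 1896 fell in both, against 1358.8 (odds ratio 2.70, interval 2.48 to 2.94, Fisher's exact test p = 8.36e-118). Another 797 rose in MDA-MB-231 and fell in 4T1, against 1285 expected, and 673 did the opposite, against 1191.8. Fold changes of the lines correlated across genes with a Pearson r of 0.334 and a Spearman rho of 0.362. Genes are not independent, so these p-values are too small. Of the gene lists, 9 passed in both lines. DNA replication fell in both, and ribosomal proteins, ATF4, MondoA and NRF2 targets, antigen presentation and autophagy rose in both. Camera was not run with library totals, where the MDA-MB-231 median of autophagy was -0.19. None of the 9 lists kept its calls with an estimated correlation, where they had adjusted p = 0.28 to 0.557 in MDA-MB-231 and 0.619 to 0.683 in 4T1. As given above for MDA-MB-231, calls were lost there even without a higher correlation, so the part of correlation in the losses cannot be told. Mitosis and cholesterol synthesis moved in opposite directions.

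The fourth comparison asked which genes changed the use of their exons. In MDA-MB-231, 4217 of 11683 genes passed, with 12232 risen and 6577 fallen parts of 207536. In PTK2, the focal adhesion kinase gene, part 106 (chromosome 8, 140879162 to 140879440, an untranslated part) rose from 0.029 and 0.048% of the gene's part counts at pH 7.4 to 3.02 and 2.89% at pH 6.4, or by 6.22 on the log2 scale relative to the gene. Part 10 of HNRNPH1 (chromosome 5, 179614960 to 179615545), annotated only as retained intron, rose by 3.98, and part 59 of DLG1 (chromosome 3, 197282610 to 197282678), of the same kind, by 8.25. Part 37 of SUPT16H (chromosome 14, 21382975 to 21383769), annotated as coding, went from 0.127 and 0.197% to 22.3 and 24.0% of the gene. Part 48 of HNRNPM (chromosome 19, 8488067 to 8488690), in a non-coding transcript, rose by 7.24 and part 66 of HNRNPU by 5.07. CD44 passed: part 89 rose by 3.86 relative to the gene, from 0.076 and 0.083% to 1.14 and 1.18%, while part 100 fell by 1.83, from 14.9 and 15.6% to 3.71 and 4.76%. ENAH missed the threshold, with a gene-level adjusted p of 0.075 in edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment. Parts of CD44 and HNRNPU could not be placed.

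Retained introns rose as a class in MDA-MB-231. Of 8066 tested parts found only in retained-intron transcripts, 3942 rose relative to their gene and 145 fell, with a median of 1.60 (log2). Other non-coding parts rose as well, 1692 of 7694 against 264 that fell, with a median of 0.30. Of 138645 coding parts 3227 rose and 3957 fell, with a median of -0.13, and of 32453 untranslated parts of coding transcripts 2120 rose and 1564 fell, with a median of 0.00. Retained-intron parts held 1.55 and 1.81% of the part counts at pH 6.4 and 0.462 and 0.48% at pH 7.4. Without pH 6.4 replicate 1, 7871 genes passed the exon test, 1567 passed without pH 7.4 replicate 1, and 1554 without pH 7.4 replicate 2.

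**Figure D3:**
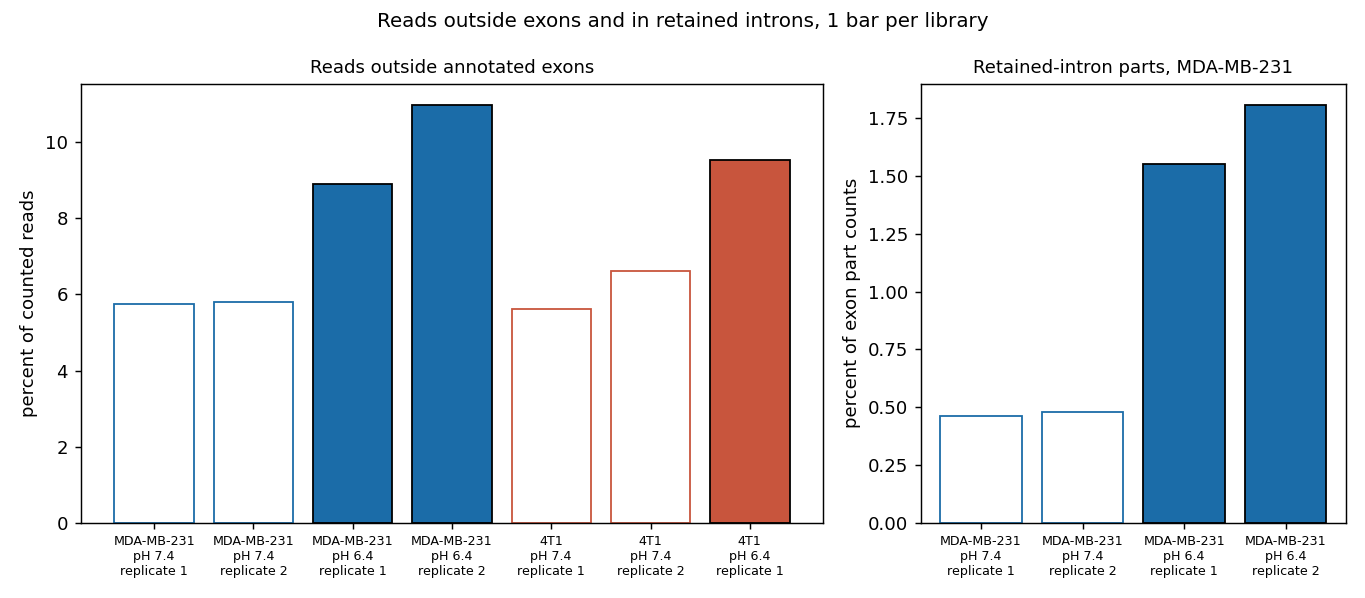
Left, reads outside annotated exons as a percentage of exon-level counts (y axis, labelled counted reads) in each of the 7 libraries. The x axis has 1 bar per library, filled at pH 6.4 and open at pH 7.4. A read can add to several exon parts, so the percentage of reads may be higher. Right, counts in retained-intron parts as a percentage of exon part counts in the 4 MDA-MB-231 libraries. Every pH 6.4 library lies above the pH 7.4 libraries of its line.

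In 4T1, 4141 of 11500 genes changed exon usage, with 8488 risen and 9279 fallen parts of 182330. Part 73 of the nuclear pore gene Tpr rose by 4.17 on the log2 scale relative to its gene, part 63 of the fibronectin gene Fn1 by 4.40, part 61 of Dst by 4.43, part 26 of Pikfyve by 5.06, part 5 of Sptbn1 by 3.52 and part 8 of 2310035C23Rik by 6.52. Part 35 of Enah rose by 3.88, with 15 counts at pH 6.4 against a mean of 4, and the gene passed with an adjusted p of 0.000159 in edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment. Cd44 missed the threshold at 0.0756 in that test. Of the genes named for MDA-MB-231, the 4T1 counterparts of PTK2, HNRNPH1, DLG1, HNRNPU and HNRNPM passed as well, and of those named for 4T1 the human DST and SPTBN1 did, while TPR, FN1 and PIKFYVE did not. Parts were not matched across species. The most changed 4T1 part fell in DLG1 (-1.65) and HNRNPM (-1.01) and rose in PTK2 (0.68), HNRNPH1 (1.76) and HNRNPU (4.33). Of the 8825 genes tested in both lines, 3683 passed in MDA-MB-231 and 3679 in 4T1. Exon usage changed in both lines for 1963 of 8825 genes, against 1535.4 expected of independent lists (odds ratio 2.28, Fisher's exact test p = 4.42e-78). Genes are not independent, so this p-value is too small. The calls carry no direction, and the read depth and number of tested parts of a gene were not taken into account. The overlap therefore does not show that the same exons changed in both lines.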

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

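The tests of low counts, of genomic DNA in either line and of mt-Co3 were chosen only after those patterns had been seen, as was the test of list differences between lines.

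The named genes below differed in their response between the lines, by the interaction of line and pH. The log2 pH effect was higher in MDA-MB-231 than in 4T1 by 4.28 for SAT1, 4.36 for TM4SF1, 5.31 for IDI1, 4.53 for MYC, 4.40 for DUSP6 and 4.47 for HMGCS1. It was lower in MDA-MB-231 for NQO1 (-5.09), AURKA (-3.98), HYLS1 (-4.60), MCM4 (-3.40), MCM3 (-4.10), MKI67 (-1.83), LDHA (-1.63) and VEGFA (-0.93). It was also higher in MDA-MB-231 for LAMP2 (0.84), MMP14 (1.47), CD44 (1.75), ENAH (2.76) and TXNIP (0.65). CD44 stood at -1.77 in 4T1, while its MDA-MB-231 value of 0.16 did not pass. Adjusted p-values of these 19 differences ran from 4.54e-09 (NQO1) to 0.0141 (TXNIP) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

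Of 40 lists, 15 differed in their pH effect between the lines by camera on the interaction. The median difference was above 0 for cholesterol synthesis (2.37), splicing regulators (0.88), ER chaperones (1.486), immediate early genes (2.484), inflammatory cytokines (2.419), lysosome genes (0.609), ribosome biogenesis (0.66), fatty acid synthesis (1.206), mitochondrially encoded transcripts (1.274), collagens (1.199) and hypoxia genes (0.834). It was below 0 for mitosis (-1.489), DNA replication (-1.385), interferon-stimulated genes (-2.396) and oxidative phosphorylation (-0.728). Camera adjusted p-values were 1.12e-11 (mitosis) to 0.025 (hypoxia), and 0.143 to 0.685 with an estimated correlation, so none held there.

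Reads outside annotated exons were used by no comparison of gene expression. They made up 8.9 and 10.99% of the exon-level counts in the MDA-MB-231 libraries at pH 6.4 and 9.52% in that of 4T1. These shares lay above each control of the same line. In MDA-MB-231 retained-intron parts rose with them. Genomic DNA would raise silent genes too. The shares outside exons had a ratio of 1.722, which silent genes would match only if all those reads were DNA. Olfactory receptor genes had 6 and 0 counts at pH 6.4 against 31 and 43, a ratio of 0.113. This fall argues against genomic DNA as the main source. A few genes taking most of the counts would leave the parts of a gene in proportion, while retained-intron parts rose by a median of 1.599 (log2) relative to their own genes, which argues against that explanation. An effect of low pH on unspliced RNA and a difference in RNA extraction between the pH groups both stay open and were not tested.

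In 4T1 the same measure may have another source. Olfactory receptor counts were 386 at pH 6.4 against 243 and 266, a ratio of 2.064 relative to library totals. This lies above 1.558, the ratio of the shares outside exons. Silent genes would match that ratio only if all reads outside exons were DNA, so it is no exact requirement. However, of 1105 receptor genes only 34 had counts at pH 6.4, against 24 and 24. Olfr920 (140 against 90 and 78) and Olfr889 (89 against 4 and 9) held 36.3 and 23.1% of the receptor counts, so much of the ratio rests on them. Genomic DNA therefore stays a possible source that this ratio cannot decide, and transcription of single genes stays open too. With 1 library at pH 6.4, an effect of pH was not separable from that library.

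Short genes lay higher and long genes lower at pH 6.4 in MDA-MB-231, with a rank correlation of fold change and transcript length of -0.222 across genes. Low counts would weaken this in abundant genes, but the correlation was -0.319 in the 20% of genes with the highest counts, which argues against low counts as the cause. Fragmented RNA could lower coverage towards the 5 prime end: the 5 prime to 3 prime log2 ratio of coding parts changed by -0.19, but the libraries at -0.861 and -1.203 at pH 6.4 and -0.836 and -0.893 at pH 7.4 did not separate beyond their spread in both replicates. The change was -0.219 in the 10% of genes with the shortest transcripts and -0.014 in the 10% with the longest, whose levels fell most, which goes against lost 5 prime coverage. The spread within these groups was not computed and only 1 pH 6.4 library lies clearly below the controls, so fragmentation and an effect of pH on transcripts of different length cannot be told apart.

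The 4T1 gene mt-Co3 had 2 counts at pH 6.4, while Gm29216 rose from 1058 and 874 to 26732. If reads had only been divided differently between them, their sum would have moved with the other mitochondrial mRNAs, but it exceeded their median by 2.667 on the log2 scale (2.413 against -0.254). A different division of reads may explain part of the fall of mt-Co3 and cannot be told apart from a change of Gm29216 itself, since the same reads were not traced to either.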

How the results depend on the processing

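Scaling by library totals, removal of the length trend and the 4T1 list fits without 1 library were chosen after seeing the data.

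In MDA-MB-231, 7264 to 11625 genes passed under the 15 alternatives, against 10170. In DESeq2 91.7% of those genes were kept. With library totals 326 called genes changed direction and were called again, and with the length trend removed 96 did. The cause was not tested. CD44 turned to -0.51 with library totals, and DUSP6 and MMP14 lost their calls there. Without 1 library, 7735 to 11625 genes passed.

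In 4T1, 5649 genes passed against a fold of 1.5, where the alternative itself asks for larger changes, and 5615 to 5733 without 1 pH 7.4 library, where a joint fit of both lines was used, against 6726 in that fit with all libraries and 9195 in the fit of 4T1 alone. The other alternatives gave 6726 to 9230. The calls kept in DESeq2 were 73.6%. In each of these fits the lone pH 6.4 library was assumed to vary like the others. No paired analysis was possible in 4T1 because its groups share only replicate number 1.

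For MDA-MB-231, a block of same-numbered replicates gave 9563 genes, 3264 genes with changed exon usage and 21 lists. The deviations of same-numbered libraries correlated with -0.032 across genes, and no label says that they were paired.

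The difference between the lines counted 5181 to 6935 genes under other scalings, tests and filters and 5373 to 6858 without 1 library, against 6312. The overlap counted 2909 to 3579 genes, against 3618.

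Exon usage in MDA-MB-231 counted 1554 to 7871 genes without 1 library, against 4217: 7871 without pH 6.4 replicate 1, 4948 without pH 6.4 replicate 2, 1567 without pH 7.4 replicate 1 and 1554 without pH 7.4 replicate 2. The cause was not tested. Its other alternatives gave 3264 to 4988, and those of 4T1 3302 to 5758, against 4141. In 4T1, leaving out a library was not run for exons, since no residual degrees of freedom would be left and parts cannot be matched across species for a joint fit.

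With an estimated correlation camera called 0 of 16 MDA-MB-231 lists and 0 of 17 4T1 lists, with 7 and 0 lists at an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 33 lists passed in MDA-MB-231 and 0 in 4T1, with 34 and 14 at an unadjusted p under 0.05. The 16 and 17 calls were kept in limma-voom, with a filter of 1 CPM and without each MDA-MB-231 library or each pH 7.4 library of 4T1 in turn, and the 16 also in the block and with the length trend removed. Length could not be removed in 4T1, as too few genes had a length, so those alternatives were not run. With an estimated correlation, calls of 4T1 were also lost where the estimate lay below the preset value, as for cholesterol synthesis (-0.043). Other estimates lay above it, such as 0.326 for ribosomal proteins. Losses with a low estimate do not come from a higher correlation. Where the estimate lay above the preset value, correlation may have added to the loss, but how much cannot be told in either line.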

Other observations

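The splits of retained-intron parts and of gene types below were chosen after the data had been seen. Of all retained-intron parts tested in MDA-MB-231, 48.9% rose relative to their genes. Differences of gene groups from this share were not tested. Of 43 such parts in ribosome biogenesis genes 34 rose and none fell, with a median of 2.32 (log2). In splicing regulators 124 of 188 rose and 6 fell (median 1.64), in ribosomal protein genes 70 of 114 (2.28), in oxidative phosphorylation genes 32 of 50 (2.15), in cholesterol genes 20 of 32 (2.52) and in lysosome genes 39 of 75 (2.13), of which 1 fell. In mitosis genes 12 of 25 rose (median 1.35), in integrin genes 11 of 25 (1.34), in ER chaperones 12 of 30 with 2 fallen (1.17) and in autophagy genes 10 of 28 (1.28). The change of retained introns relative to their gene was only loosely related to the fold change of that gene. The Spearman rho was 0.101 and the Pearson r 0.122 across 3182 genes, which are not independent replicates. The gene's own change is already taken out of the relative value. This therefore does not show that retained-intron levels moved apart from the levels of their genes.

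Gene types moved apart in MDA-MB-231. Of 79 ribosomal protein pseudogenes 48 rose and 1 fell, with a median log2 fold change of 1.55, near the 1.44 of the ribosomal protein genes whose reads they can share. Sense intronic genes rose in 58 of 135 cases and fell in 18 (median 1.21). Of 12447 protein-coding genes 4091 rose and 4815 fell (median -0.16), and of 540 antisense genes 89 rose and 146 fell (median -0.62).

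Lists that did not pass in MDA-MB-231 had these risen and fallen genes. Integrins had 5 and 13 of 24 and mitochondrial transcripts 9 and 1 of 15. p53 targets had 11 and 3 of 20, interferon genes 5 and 17 of 33 and oxidative phosphorylation 18 and 4 of 34. Apoptosis regulators had 10 and 6 of 19, epithelial markers 2 and 8 of 16, and fatty acid oxidation 7 and 6 of 22. TGF-beta targets had 8 and 6 of 18, mesenchymal markers 6 and 3 of 11, histones 7 and 1 of 11, YAP targets 5 and 12 of 18 and heat shock genes 7 and 3 of 12. Actin motility had 17 and 7 of 29 (17 and 8 adjusted over the list alone), S100 genes 4 and 1 of 8 and cholesterol efflux 2 and 3 of 6. Fibroblast markers had 2 and 1 of 5, leukocyte markers 1 and 1 of 3, glycolysis 5 and 11 of 21 (6 and 11 adjusted over the list alone), the citric acid cycle 7 and 9 of 20, collagens 10 and 11 of 28 and fatty acid synthesis 6 and 6 of 15. Camera adjusted p-values were 0.06 to 0.973, and counts adjusted over the list alone were otherwise the same. With library totals 13 medians of that line changed sign, and 2, those of the citric acid cycle and fatty acid oxidation, with DESeq2 size factors. Median, mean and test differed in sign for fatty acid oxidation, cholesterol efflux, collagens and fatty acid synthesis.

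In 4T1 the lists that did not pass were these. Mitochondrial transcripts had 4 risen and 6 fallen of 15, mesenchymal markers 1 and 6 of 11 (2 and 6 adjusted over the list alone), fibroblast markers 1 and 2 of 5 (1 and 3) and epithelial markers 3 and 12 of 22. Histones had 0 and 3 of 5, the citric acid cycle 10 and 5 of 20 (11 and 5), S100 genes 3 and 1 of 10 and cholesterol efflux 1 and 2 of 7. Glycolysis had 5 and 9 of 21, ER chaperones 7 and 7 of 21, apoptosis regulators 6 and 6 of 19 and hypoxia genes 6 and 9 of 21 (6 and 10). TGF-beta targets had 6 and 8 of 18, inflammatory cytokines 12 and 12 of 32, YAP targets 6 and 9 of 18 and actin motility 10 and 8 of 26 (10 and 9). Immediate early genes had 7 and 8 of 21, ribosome biogenesis 10 and 12 of 32 and leukocyte markers 2 and 2 of 4. Camera adjusted p-values were 0.0626 to 0.973. Median, mean and test differed in sign for apoptosis regulators, actin motility and ribosome biogenesis.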
